A study of Homo sapiens with 16 samples.

How the data were processed

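The series holds polyA RNA from human induced pluripotent stem cells (iPSCs) of the WTC11 line, called WTC here, and of lines made from it that carry a doxycycline-inducible CRISPR vector. CRISPRn cells carry the Cas9 nuclease, which cuts DNA where a single guide RNA (sgRNA) directs it. CRISPRi cells carry a catalytically dead Cas9 joined to the KRAB repressor domain (dCas9-KRAB), which lowers transcription where an sgRNA directs it. Doxycycline is an antibiotic that switches on promoters bound by the reverse tetracycline transactivator (rtTA). The remaining line, called sgGCaMP here, is labelled as CRISPRi with an sgRNA against the calcium reporter GCaMP6f, and its libraries also hold counts of a row named ACTN2mKate. Each of the 4 lines was sampled without and with doxycycline, which gave 8 groups of 2 libraries and 16 libraries in all. The dose and the time of doxycycline are not given in the sources used here.

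Per the labels' protocols, RNA was extracted with TRIzol and strand-specific libraries were made with an Illumina TruSeq Stranded mRNA kit. Per the submitters' processing notes, bcl2fastq, TopHat2 2.1.0 and Subread 1.4.6 were used with the hg19 genome, and the notes give neither their order nor their settings. The deposited table held whole-number read counts per gene, not normalized, with 64705 rows and no value that was not whole. The gene annotation and whether the counting used strand are not given in the sources used here, so counts of overlapping and antisense genes are uncertain. Of the rows, 63677 had Ensembl IDs, and 52526 of these were given a symbol: 52181 from a name table and 345 from GENCODE 29, which was used for names only. A further 930 rows with the prefixes NLG_ and TUCPG_ held 0.084% to 0.153% of the counts, 90 rows for ERCC spike-in controls held 0 counts, and 8 rows named constructs. The cells of 6 construct rows were blank for lines without that vector and were treated as missing. Coordinates are those of the deposited table, per the file headers, in hg19. The deposited length column, the bases of the exons of each row, was not used for normalization.

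Library totals ranged from 4338804 to 11142545 counts. In all 8 groups replicate A was the deeper library. Within groups the spread between libraries exceeded counting error, with a mean chi-square per degree of freedom of 2.41 to 4.38. The design text names 2 biological replicates per group, and nothing in the sources used here says that they were separate cultures, so all p-values measure the spread between these samples, which may be technical. Intervals of ratios of counts, and floors, cover counting error alone, at the 95% level, because reads without molecular identifiers are not independent molecules. A floor is 3 counts over a group.

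From the deposited counts, edgeR 4.0.16 in R 4.3.3 was used to keep 15759 genes by filterByExpr (minimum count 10, minimum total 15, here 1.45 CPM), to normalize by the trimmed mean of M values (TMM, factors 0.949 to 1.038) and to fit 1 quasi-likelihood model with a mean for each of the 8 groups over all 16 libraries, with 8 residual degrees of freedom. The biological coefficient of variation was 6.3%. Contrasts gave the doxycycline effect in each line, its mean over the 4 lines, the difference of the effect between lines (interactions of CRISPRn with WTC, CRISPRi with WTC, and sgGCaMP with CRISPRi), and the line differences. All p-values for genes are two-sided quasi-likelihood p-values from edgeR adjusted by Benjamini and Hochberg, and a gene was said to rise, fall or differ at an adjusted p under 0.05. Levels of genes are means of counts scaled to a common library total after TMM normalization (CPM), computed from the deposited counts. Errors of log2 fold changes are standard errors (SE) with 2 libraries in each group. Rows blank in some lines were tested in separate fits, over the 8 libraries with the CRISPRi vector or the 4 CRISPRn libraries. CPM values of construct rows are shares of the library total, without the TMM factors.

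Lists of genes, 25 in all, were tested with camera in limma 3.58.1 at a preset correlation of 0.01, with fry beside it, and adjusted over the lists within each comparison. Values of fry are given only for mitochondrial mRNAs in WTC. The lists were pluripotency; markers of mesendoderm and endoderm, of neuroectoderm and neurons, of fibroblasts and mesenchyme, of trophoblast and amnion, and of cardiomyocytes; p53 targets; mitochondrially encoded mRNAs; the nuclear-encoded respiratory chain; the mitochondrial ribosome; ATF4 and the integrated stress response; the endoplasmic reticulum (ER) unfolded protein response; interferon-stimulated genes; cholesterol biosynthesis; glycolysis and hypoxia; heat shock; immediate early genes; G2 and mitosis; DNA replication; imprinted genes; neighbours of the AAVS1 site; KRAB corepressor partners; metal response; zinc finger genes with a ZNF symbol; and cytosolic ribosomal proteins. Camera asks whether a list stands apart from the other genes. Each camera p was computed again with a correlation estimated from the data. With that correlation the calls that held were pluripotency for doxycycline in CRISPRi, in sgGCaMP, over the 4 lines and in the CRISPRi interaction and for sgGCaMP against CRISPRi; mitochondrial mRNAs in WTC; metal response for doxycycline in CRISPRi and in the 3 comparisons of CRISPRi with WTC or sgGCaMP; mesendoderm and heat shock for doxycycline in sgGCaMP, and mesendoderm in the sgGCaMP interaction and in CRISPRi against WTC; ATF4 and imprinted genes in both lines against WTC; p53 targets in CRISPRi against WTC and in sgGCaMP against CRISPRi; cholesterol in sgGCaMP against CRISPRi; and immediate early genes in the latter with doxycycline.

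The groups, comparisons, tests, lists, naming rule and all but 2 of the alternatives were fixed before the data were examined. The rule named, for each comparison, the construct rows, PPP1R12C (which holds the AAVS1 integration site), up to 10 genes that rose and up to 10 that fell with the smallest adjusted p and no overlap between the libraries of both groups (for the mean effect, one sign in all 4 lines), up to 4 members of each list called and up to 3 of the most abundant members of other lists. Genes named outside this rule are said to be so, and 3 genes that it named are not reported here. For genes with 1 to 3 counts in a group, the ratio of counts is given with its counting interval, and against 0 counts a lower bound computed from the floor. Each named gene was checked for another row that shared at least 10% of its bases and counts: 15 of 324 had one, of which 11 lay on the opposite strand. Metallothioneins, heat shock HSPA1 genes, ribosomal proteins, ZNF genes and mitochondrial genes with nuclear copies share near-identical sequence, so their separate values are uncertain.

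The alternatives were RLE normalization, no filter, DESeq2 1.42.0, the replicate letter as a block, a fit of the compared groups alone, each library left out in turn, and camera with an estimated correlation. Libraries thinned to the smallest total, and a fit with line and doxycycline as terms, were chosen after seeing the data. The fits were tested on simulated data before use, with 1.5-, 2- and 4-fold changes planted in known genes (random seed 1). For the doxycycline effect in CRISPRi, over 15265 simulated genes, 46.3%, 82.1% and 89.4% of these were recovered at the 3 sizes and 4.2% of calls were false. For the mean effect, over 15274 genes, 82.1%, 94% and 98.5% were recovered with 2.7% false. For the CRISPRi interaction, over 15277 genes, 11.9%, 67.2% and 83.3% were recovered with 6.1% false, and for CRISPRi against WTC, over 15287 genes, 52.2%, 68.7% and 97% with 6.5% false. A planted shift of the heat shock list was called at an adjusted p of 4.5e-43, and at 9.4e-06 with an estimated correlation, and 0 of the other lists were called. Tables and figures were made in Python 3.11.15 with pandas 2.3.3, numpy 2.4.6 and matplotlib 3.10.9. X-inactivation and Y-linked genes were not reported, and sequence-level data were not analysed here.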

Results

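Read counts per gene were compared in 4 human iPSC lines, each without and with doxycycline and with 2 libraries per group. The parental WTC libraries held 6847611 and 5519694 counts without doxycycline (replicates A and B) and 7942621 and 5159001 with it. CRISPRn held 6184073 and 4338804 counts without and 9849606 and 7686150 with doxycycline. CRISPRi held 7024469 and 5156841 counts without and 7992981 and 5636203 with it, and sgGCaMP 11142545 and 7328528 without and 8472611 and 6056014 with it. Mitochondrial rows took 5.79% to 9.55% of the counts, and the 10 most abundant rows 6.21% to 9.43%. Principal components separated the lines more than doxycycline did. The first carried 52.0% of the variance and parted WTC and CRISPRn from both CRISPRi lines. The next carried 14.2% and parted sgGCaMP from CRISPRi.

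**Figure D1:**
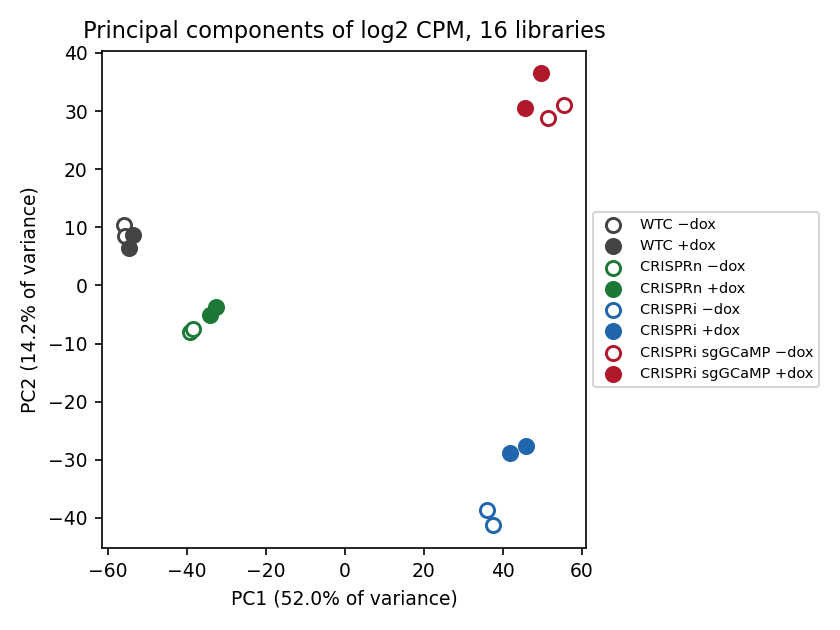
Principal components of log2 CPM over the 16 libraries, with the percent of variance on each axis (52.0% and 14.2%), 1 point per library, open without doxycycline and filled with it, coloured by line. WTC and CRISPRn lie on the left, CRISPRi at the lower right and sgGCaMP at the upper right.

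The first question was whether the vectors were switched on and whether dCas9-KRAB with its guide lowered its target. With doxycycline, GCaMP6f, a fluorescent calcium reporter and the target of the guide, fell in sgGCaMP from 682.6 ± 73.9 to 18.1 ± 2.9 CPM (SD, n = 2), that is from 12809 to 258 counts. This left 2.56% of the level without doxycycline (95% counting interval 2.26% to 2.90%), a reduction of 97.4% (log2 fold change −5.33, SE 0.12, edgeR adjusted p = 4.45e-38). That interval leaves out the spread between libraries, which read 734.9 and 16.05 CPM without and with doxycycline in replicate A and 630.4 and 20.15 in B. In CRISPRi without the guide, GCaMP6f read 491.2 ± 38.7 CPM before and 419.8 ± 2.97 CPM after doxycycline, a difference that did not pass the test (log2 fold change −0.26, adjusted p = 0.0677). The doxycycline effects on GCaMP6f in both lines differed by a log2 value of −5.06 (interaction adjusted p = 2.17e-32). WTC and CRISPRn groups held 1 to 3 GCaMP6f counts each.

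The effector rows followed doxycycline. KRAB-dCAS9-P2A-mCherry, the repressor joined to a red fluorescent protein, went from 2 to 13488 counts in CRISPRi, a ratio of 6028 after scaling (1668 to 49780), and from 3 to 11297 counts in sgGCaMP, a ratio of 4788 (1638 to 23220). With doxycycline it reached 986.7 ± 25.9 CPM in CRISPRi and 784.6 ± 60.5 CPM in sgGCaMP (SD, n = 2), lower in sgGCaMP (log2 fold change −0.39, adjusted p = 0.000406). Cas9 in CRISPRn went from 5 to 5135 counts, a 616-fold rise (264 to 1899), to 293.2 ± 3.46 CPM. The resistance genes of both vectors also rose: NeoR_KanR by log2 1.94 in CRISPRi and 1.73 in sgGCaMP, and PuroR by 1.43 in CRISPRn. The transactivator row rtTA3G_CRISPRi rose from 121 to 354 CPM in CRISPRi (log2 1.51) and from 96.8 to 444 CPM in sgGCaMP (log2 2.13), while rtTA3G_CRISPRn read 373 and 335 CPM (adjusted p = 0.393). ACTN2mKate, a row named after the sarcomere gene ACTN2 and a red fluorescent protein, had 2154 and 1193 counts in sgGCaMP without and with doxycycline and 0 to 3 counts in each other group. It fell with doxycycline in sgGCaMP (log2 −0.56, adjusted p = 0.000484). Leaving out sgGCaMP with doxycycline replicate A raised that adjusted p to 0.0605.

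**Figure D2:**
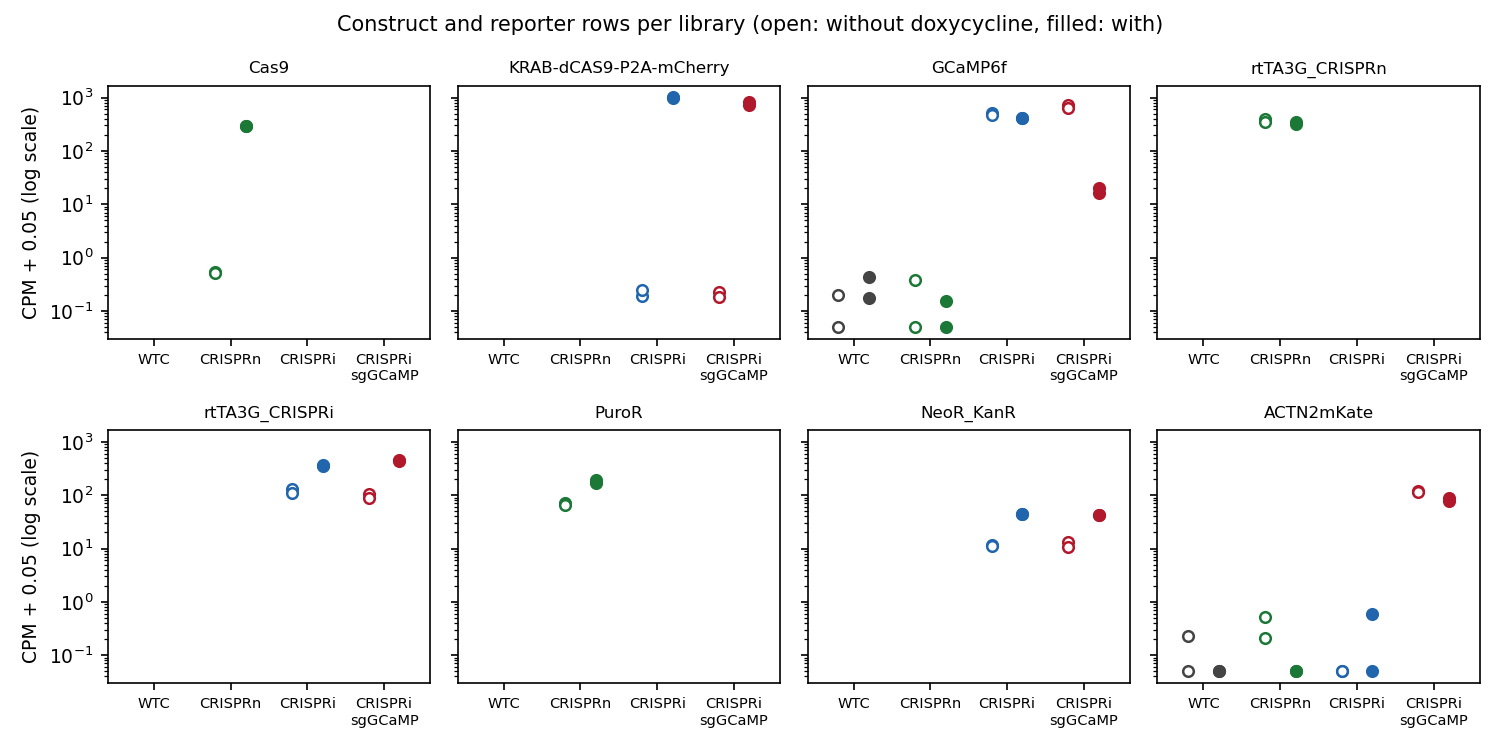
CPM of the library total, plus 0.05, on a log axis for the 8 construct rows, 1 point per library, by group (n = 2). GCaMP6f drops to 18.1 CPM on average in sgGCaMP with doxycycline, Cas9 and KRAB-dCAS9-P2A-mCherry appear with doxycycline, and lines without a value for a row are left blank.

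Doxycycline in WTC, which carries no vector, asks what the drug itself did. Mitochondrial transcripts rose: MT-ATP6, a subunit of ATP synthase, by a log2 value of 0.67 (SE 0.08, adjusted p = 7.35e-07), and MT-CO2, a subunit of cytochrome c oxidase, by 0.52 (SE 0.08, adjusted p = 8.64e-05). MT-ATP8, MT-CYB and MT-CO3 rose by 0.68, 0.42 and 0.42, and MTATP6P1, a nuclear copy of mitochondrial sequence, by 0.61. MT-ATP6 and MT-ATP8 overlap in the genome, and MTATP6P1 is near-identical to MT-ATP6, so their values are not separate. These 6 genes were all that passed over the 15759 tested by edgeR, and 749 had an unadjusted p under 0.05 where chance gives 788. The mitochondrial share of counts was 5.79% and 6.43% without and 7.56% and 7.49% with doxycycline.

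As a list, mitochondrial mRNAs stood above the other genes in WTC with doxycycline (5 of 13 rose, 10 adjusted over the list alone, camera adjusted p = 4.31e-38, adjusted p = 0.0217 with an estimated correlation). For this list fry gave an adjusted p of 0.108 for a change in one direction and 0.0195 for changes in either direction. Lists of the nuclear-encoded respiratory chain (1.89e-09), cytosolic ribosomal proteins (3.27e-11), the mitochondrial ribosome (0.00916) and pluripotency (0.0135) were also called up and ATF4 (0.0173) down, with 0 members past the edgeR test in any of them. Their median log2 changes were 0.16, 0.11, 0.09, 0.07 and −0.10. These 5 calls had adjusted p = 0.400, 0.812, 0.812, 0.400 and 0.851 with an estimated correlation. Without WTC without doxycycline replicate A, 1 gene passed in place of 6, and adjusted p was 0.0775 for MT-CO2, 0.366 for MT-ATP8, 0.466 for MT-CYB, 0.860 for MT-CO3 and 0.951 for MTATP6P1. MT-CYB also lost its call without either library with doxycycline (0.191 and 0.0766 without A and B), MT-CO3 without any of the other libraries, and MTATP6P1 without replicate B with doxycycline (0.134). Leaving out that library left 3 genes. DESeq2 called 3, and not MT-ATP8 (0.576), MT-CO3 (0.0707) or MTATP6P1.

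In CRISPRn without a guide, the doxycycline comparison holds the induced nuclease, the drug itself and the activated rtTA together. The interaction with WTC, given further below, takes off the effect of doxycycline seen in WTC. VIM, which encodes the intermediate filament vimentin (chromosome 10, 17270258 to 17279592), rose from 138.2 to 328.3 CPM (2.37-fold, SE of log2 0.09, adjusted p = 2.67e-15). PPP1R12C, which holds the AAVS1 site (chromosome 19, 55602281 to 55628927), rose by 0.98 (SE 0.14, adjusted p = 2.98e-06) and its neighbour TNNT1, a troponin gene (55644162 to 55660722), by 0.64. ODC1, the rate-limiting enzyme of polyamine synthesis, rose by 0.82, NID1, a basement membrane protein, by 0.74, and CUZD1, STC1 and CLDN4 by 0.94, 0.78 and 0.68. Among genes that fell were STOM (−1.40), the glutamate transporter SLC1A3 (−1.46), PTH1R (−1.78), the WNT antagonist FRZB (−1.15), LHX4 (−1.42), HAPLN1 (−2.58) and HIP1R (−1.14).

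Pluripotency genes fell in part in CRISPRn with doxycycline: NANOG, a core transcription factor of pluripotent cells, by log2 −0.90 (SE 0.14) and L1TD1 by −0.47 (SE 0.09). Of 25 members 4 were lower and, adjusted over the list alone, 4 lower and 1 higher (camera adjusted p = 0.000804, adjusted p = 0.213 with an estimated correlation). Of 11 neuroectoderm markers the forebrain factor SIX3 (−0.91) and ZIC1 (−0.72) fell, both also when adjusted over the list alone. The list was called down at 0.0237 (adjusted p = 0.278 with an estimated correlation) although its median was 0.06 and its mean 0.02. Mitochondrial mRNAs were higher (6 of 13, 8 adjusted over the list alone, 7.53e-08, adjusted p = 0.278 with an estimated correlation), among them MT-ATP8 by 0.61, MT-ATP6 by 0.43 and MT-CO2 by 0.37. Of the 6 genes that rose in WTC with doxycycline, 5 also rose in CRISPRn, where independent lists would give 0.05. DNA replication was lower (2 of 21, 7 adjusted over the list alone, 7.89e-05, and adjusted p = 0.213 with an estimated correlation). G2 and mitosis was higher (1 of 20, 2 adjusted over the list alone, 0.000105, and adjusted p = 0.278 with an estimated correlation). ATF4 targets were higher (3 of 27, 6 adjusted over the list alone, 0.00241, and adjusted p = 0.494 with an estimated correlation). ASNS, asparagine synthetase, rose by 0.68. Called up with 0 members past the edgeR test over all genes were p53 targets (5 of 24 adjusted over the list alone, 0.00244), the nuclear-encoded respiratory chain (0.0374) and metal response (0.0171). These had adjusted p = 0.213, 0.668 and 0.432 with an estimated correlation. AAVS1 neighbours (2 of 21, 3 adjusted over the list alone, 0.00623) and mesenchymal markers (2 of 13 higher and 1 lower, 4 and 2 adjusted over the list alone, 0.0273) were called up, both with adjusted p = 0.432 with an estimated correlation. Without CRISPRn without doxycycline replicate A, the adjusted p was 0.114 for MT-ATP8, 0.146 for MT-ATP6, 0.231 for MT-CO2 and 0.137 for ASNS.

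In all, 141 genes rose and 220 fell in CRISPRn with doxycycline, 32 and 31 of them by over 2-fold, and 2234 had an unadjusted p under 0.05. The 361 calls became 80 without CRISPRn without doxycycline replicate A, 173 without its replicate B and 164 without CRISPRn with doxycycline replicate B, and DESeq2 made 219.

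In CRISPRi without a guide, the same comparison holds dCas9-KRAB without a target, the drug itself and the activated rtTA together. VIM rose from 56.8 to 246.6 CPM (log2 2.11, SE 0.09, adjusted p = 2.55e-23), DUSP6, a phosphatase that restrains ERK signalling, by 1.53 (SE 0.11, adjusted p = 3.58e-15). The actin-binding TAGLN rose 2.30-fold. CALD1, another actin-binding protein, rose by 0.62, ID3 by 0.71, the secretory granule protein CHGA by 1.11, DTNA by 0.94, PRTG by 1.10 and MSN by 0.52. PLAAT3 fell by 1.11, the proline dehydrogenase PRODH by 1.04, ESYT2 by 0.96, the metalloproteinase MMP24 by 1.64, SERPINB9 by 1.07 and STOM by 1.29 on the log2 scale. TAGLN overlaps PCSK7 and MMP24 overlaps MMP24OS on the other strand.

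Pluripotency genes fell in CRISPRi with doxycycline, 11 of 25 (13 adjusted over the list alone, camera adjusted p = 5.83e-11, adjusted p = 0.0191 with an estimated correlation). NANOG read −0.48 (SE 0.09) on the log2 scale and the telomere protein TERF1 −0.41. Metal response fell as a list (7 of 14 lower and 1 higher, 8 and 1 adjusted over the list alone, 4.52e-13, adjusted p = 0.0340 with an estimated correlation). The metallothioneins MT1H, MT1G, MT1X and MT2A, which bind zinc and copper, read −1.25, −1.13, −0.99 and −0.97. Heat shock was lower (3 of 16, 5 adjusted over the list alone, 1.30e-05, adjusted p = 0.0807 with an estimated correlation). The chaperone HSP90AA1 read −0.48. Cytosolic ribosomal proteins were lower (11 of 81, 42 adjusted over the list alone, 4.55e-19, adjusted p = 0.313 with an estimated correlation). ATF4 targets were lower (3 of 27, 5 adjusted over the list alone, 0.00122, adjusted p = 0.494 with an estimated correlation). The amino acid transporter SLC7A5 read −0.72. Cholesterol genes were higher (5 of 23 up and 1 down, 9 and 1 adjusted over the list alone, 0.00137, adjusted p = 0.450 with an estimated correlation). MSMO1, a sterol oxidase, read 0.46. Glycolysis and hypoxia genes (4 of 25, 6 adjusted over the list alone, 0.000243) and G2 and mitosis genes (1 of 20, 5 adjusted over the list alone, 0.00169) were higher. Both had adjusted p = 0.369 with an estimated correlation. The glucose transporter SLC2A1 rose by 0.55 and the kinetochore motor CENPE by 0.52. Among the other calls, p53 targets were lower (2 of 24, 5 lower and 1 higher adjusted over the list alone, 0.0433, adjusted p = 0.313 with an estimated correlation). The nuclear-encoded respiratory chain was lower with 0 members past the edgeR test (0.00533, adjusted p = 0.494 with an estimated correlation). Of 6 trophoblast markers 1 fell when adjusted over the list alone and 0 over all genes (0.0298, adjusted p = 0.205 with an estimated correlation). Of 13 mesenchymal markers 2 rose and 2 fell, the same adjusted over the list alone (called up at 0.0419, adjusted p = 0.396 with an estimated correlation). Without CRISPRi with doxycycline replicate B, adjusted p was 0.151 for MSMO1 and 0.0710 for SLC2A1.

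Over all genes 264 rose and 418 fell in CRISPRi with doxycycline, 45 and 76 by over 2-fold, and 2688 had an unadjusted p under 0.05. The 682 calls became 195 without CRISPRi with doxycycline replicate B, 365 and 446 without CRISPRi without doxycycline replicates A and B, and 434 with DESeq2.

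In sgGCaMP, doxycycline brought the guide and dCas9-KRAB together. Besides GCaMP6f, VIM rose from 100.2 to 725.2 CPM (log2 2.86, SE 0.09, adjusted p = 1.93e-31). MXD4, an antagonist of MYC, rose 2.82-fold. ISLR rose by a log2 value of 1.72, the planar polarity gene PRICKLE1 by 1.99, CLIP3 by 1.26, the translation inhibitor PDCD4 by 1.16 and the somatostatin receptor SSTR1 by 2.83. Genes that fell included IER3 (−1.64), NODAL, a ligand that keeps human pluripotent cells undifferentiated (−1.61, SE 0.13, adjusted p = 1.64e-13), PLAAT3 (−1.58), the RNA polymerase III subunit POLR3G (−1.18), SLC1A3 (−1.37), PDLIM1 (−1.12) and TNFRSF8 (−1.63). PDCD4 shares bases with BBIP1 on the other strand.

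Pluripotency fell in sgGCaMP with doxycycline: 15 of 25 members were lower and 2 higher (17 and 2 adjusted over the list alone, camera adjusted p = 1.18e-10, adjusted p = 0.0133 with an estimated correlation). The de novo DNA methyltransferase DNMT3B read −0.81 (SE 0.07), NANOG −0.80 (SE 0.09), L1TD1 −0.70 and GDF3 −1.07. Mesendoderm and endoderm genes fell with NODAL (4 of 10, 5 adjusted over the list alone, 1.20e-07, adjusted p = 0.0174 with an estimated correlation). The NODAL antagonist LEFTY1 read −1.44, MIXL1 −1.98 and WNT3 −1.16. Heat shock fell (10 of 16, 11 adjusted over the list alone, 4.48e-08, adjusted p = 0.0276 with an estimated correlation). The chaperones HSPA8, HSPH1 and HSPA1B read −0.65, −0.63 and −1.11. The ER unfolded protein response (7 of 16, 9 adjusted over the list alone, 0.000257) and the mitochondrial ribosome (8 of 23, 9 adjusted over the list alone, 1.56e-05) were lower. Both had adjusted p = 0.227 with an estimated correlation. The ER chaperone HSPA5 read −0.56, XBP1 −0.64 and MRPL3 −0.43. Metal response was lower (6 of 14, and 6 adjusted over the list alone, 1.13e-07, adjusted p = 0.0877 with an estimated correlation), MT2A by −1.37. Immediate early genes were lower (4 of 18, 6 lower and 2 higher adjusted over the list alone, 0.00157, adjusted p = 0.248 with an estimated correlation). MYC read −1.24 and IER2 −0.51. DNA replication was lower (7 of 21 and 1 higher, 11 and 1 adjusted over the list alone, 0.00610, adjusted p = 0.322 with an estimated correlation). G2 and mitosis was higher (4 of 20, 8 adjusted over the list alone, 0.0150, adjusted p = 0.534 with an estimated correlation). Ribosomal proteins (7 of 81, 4 adjusted over the list alone, 5.32e-05) and cholesterol genes (4 of 23 lower and 1 higher, 5 and 1 adjusted over the list alone, 0.0489) were lower, both with adjusted p = 0.644 with an estimated correlation.

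Lists without a call in sgGCaMP with doxycycline were ZNF genes (26 of 494 rose and 14 fell, camera adjusted p = 0.0994), KRAB corepressor partners (4 of 17 rose, 0.245) and, among others, interferon-stimulated genes (1 of 15 fell) and cardiomyocyte markers (1 of 5 fell). Neuroectoderm markers had a median of −0.33 as fitted and 0.35 with 1 member of few counts set to its bound. In all, 925 genes rose and 1413 fell, 167 and 185 by over 2-fold, and 4433 had an unadjusted p under 0.05. The 2338 calls became 791 without sgGCaMP with doxycycline replicate A and 1309 without sgGCaMP without doxycycline replicate A, and DESeq2 made 1503.

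**Figure D3:**
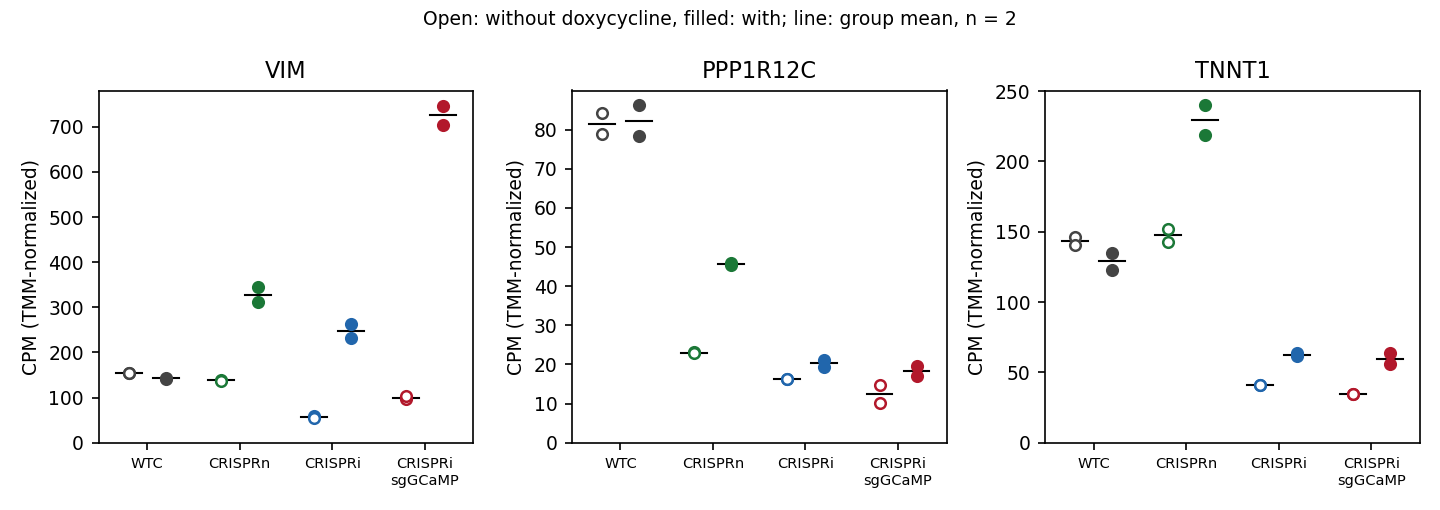
TMM-normalized CPM of VIM, PPP1R12C and TNNT1 per library (points) with the group mean (line, n = 2) for the 8 groups. VIM with doxycycline averages 328.3 CPM in CRISPRn, 246.6 in CRISPRi and 725.2 in sgGCaMP.

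Over the 3 lines with a vector, 66 genes changed in one direction with doxycycline, 11 up and 55 down, where independent lists would give 0.14 and 0.52. Those that rose included VIM, TNNT1, NID1, CHGA, ADAM9 and MSN, and those that fell NANOG, ZIC1, LHX4, STOM, SLC1A3 and FN1. In WTC, VIM read −0.12 (adjusted p = 0.985), 28 of the 66 had the same sign as in the other lines, and 1, MT-ATP8, was called. The interaction with WTC was called for 29 of the 66 in CRISPRn, 40 in CRISPRi and 22 in both. By pairs, CRISPRn and CRISPRi shared 24 genes up and 80 down (2.36 and 5.84 expected from independent lists), CRISPRn and sgGCaMP 38 and 93 (8.28 and 19.73), and CRISPRi and sgGCaMP 83 and 209 (15.5 and 37.48).

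The mean doxycycline effect over the 4 lines took up 721 genes that rose and 1079 that fell. The mitochondrial MT-ATP8 rose by log2 0.55 (SE 0.05) and MT-ATP6 by 0.42, CHGA by 0.76, NID1 by 0.49, PRICKLE1 by 0.80 and the cell cycle inhibitor CDKN1C by 0.45. DPYSL3 (−0.43, SE 0.04, adjusted p = 2.73e-12), LHX4 (−1.40), FEZF1-AS1 (−1.10), the WNT receptor FZD5 (−0.47), SIX3 (−0.94), ZIC1 (−0.52) and CPNE7 (−0.81) fell, and LHX4 overlaps ACBD6 and FEZF1-AS1 overlaps FEZF1 on the other strand. Such means can rest on some of the lines: in WTC, NID1 read 0.00 and SIX3 −0.00. Pluripotency was lower (12 of 25, 15 adjusted over the list alone, camera adjusted p = 5.99e-11, adjusted p = 0.0185 with an estimated correlation), with NANOG at −0.53. Heat shock was lower (8 of 16, 10 lower and 1 higher adjusted over the list alone, 9.28e-06, adjusted p = 0.113 with an estimated correlation). So was metal response (4 of 14, 7 adjusted over the list alone, 0.000778, adjusted p = 0.254 with an estimated correlation). Mitochondrial mRNAs (8 of 13 and 1 lower, 8 and 1 adjusted over the list alone, 3.78e-08) and G2 and mitosis (7 of 20, 8 adjusted over the list alone, 1.90e-05) were higher. DNA replication (8 of 21 and 1 higher, 13 and 1 adjusted over the list alone, 0.000148) and neuroectoderm (3 of 11 and 1 higher, the same adjusted over the list alone, 0.0238) were lower. All 4 lists had adjusted p = 0.248 with an estimated correlation. The median of mitochondrial mRNAs was 0.37 in WTC and 0.22 in CRISPRn, against 0.00 in CRISPRi and −0.08 in sgGCaMP, where the list was not called. AAVS1 neighbours were higher (4 of 21, 4 adjusted over the list alone, 0.00635, adjusted p = 0.456 with an estimated correlation). Ribosomal proteins were lower (6 of 81, 0 adjusted over the list alone, 0.000416, adjusted p = 0.728 with an estimated correlation). A fit with line and doxycycline as terms, chosen after seeing the data, called 946 genes in place of 1800.

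CRISPRn against WTC without doxycycline compares the uninduced line with its parent. ATF4 targets, which cells raise when amino acids run short, were lower in CRISPRn. All 27 members were lower in CRISPRn, 27 adjusted over the list alone, with a median log2 of −2.31 (camera adjusted p = 4.87e-210, adjusted p = 0.000147 with an estimated correlation). ATF5 read −4.25 (SE 0.15), TRIB3 −4.23, SLC7A5 −3.40, ASNS −3.38 and PSAT1, of serine synthesis, −2.60, and the tRNA synthetases GARS1, AARS1 and WARS1 read −2.13, −1.83 and −1.93. ATF5 overlaps NUP62 on the other strand. MEG3, an imprinted noncoding RNA, fell from 1345 to 15.7 CPM (log2 −6.43, SE 0.11, adjusted p = 1.01e-42), while CDKN1C, also imprinted, was higher by 1.66. PPP1R12C was lower by a log2 value of −1.82 (adjusted p = 8.41e-16). The retinoic acid binding protein CRABP2 was higher by 1.08, SERPINB9 by 1.11, the transcription factor EGR1 by 1.11 and the glycolytic enzyme PKM by 0.71, and AC117402.1 had 111 counts against 2, a 65.3-fold ratio (17.6 to 546).

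Imprinted genes were called lower in CRISPRn than in WTC (4 of 20 lower and 2 higher, 5 and 2 adjusted over the list alone, 1.82e-07, adjusted p = 0.00381 with an estimated correlation). GRB10 read −0.76 and MEST −0.66. Mitochondrial mRNAs (12 of 13, 12 adjusted over the list alone, 4.69e-10), cholesterol genes (12 of 23, 13 adjusted over the list alone, 1.03e-08) and neuroectoderm markers (4 of 11, 4 higher and 1 lower adjusted over the list alone, 0.00680) were higher. Each had adjusted p = 0.216 with an estimated correlation. MT-ATP6 read 0.51, ZIC1 0.72 and HMGCS1, which makes the precursor of mevalonate, 0.73. Called up were glycolysis and hypoxia (13 of 25 higher and 2 lower, 15 and 2 adjusted over the list alone, 0.000136) and immediate early genes (7 of 18 higher and 2 lower, the same adjusted over the list alone, 0.00720). Mesenchymal markers (4 of 13 higher and 1 lower, 6 and 2 adjusted over the list alone, 0.0178) and heat shock (5 of 16, 6 adjusted over the list alone, 0.0336) were too. So were p53 targets (9 of 24 higher and 3 lower, the same adjusted over the list alone, 0.0404) and pluripotency (6 of 25 higher and 3 lower, 8 and 4 adjusted over the list alone, 0.0471). These 6 lists each had adjusted p = 0.270 with an estimated correlation. VEGFA, an angiogenic factor on the hypoxia list, went the other way at −1.89, and COL1A1, the main fibroblast collagen, read 0.83. The nuclear-encoded respiratory chain was higher (5 of 27, 7 adjusted over the list alone, 0.00159) and DNA replication lower (5 of 21 and 1 higher, the same adjusted over the list alone, 0.0471), both with adjusted p = 0.375 with an estimated correlation. Not called were KRAB corepressor partners (6 of 17 higher and 1 lower, 0.134) and ZNF genes (17 of 494 higher and 39 lower, 0.0883). Nor were the ER unfolded protein response (4 of 16 higher and 3 lower, 0.945, with a median of 0.14, a mean of −0.04 and a test direction of up) and AAVS1 neighbours (3 of 21 higher and 1 lower, 0.646).

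In all, 1175 genes were higher and 1102 lower in CRISPRn than in WTC, 166 and 328 by over 2-fold, or 14.45% of those tested. The 2277 calls became 1100 without WTC without doxycycline replicate A, and 1145 and 1424 without CRISPRn without doxycycline replicates A and B.

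CRISPRi against WTC without doxycycline showed larger differences, and these lines differ in the GCaMP6f reporter as well as in the vector: GCaMP6f had 6034 counts in CRISPRi and 1 in WTC, a ratio of 6130 (1100 to 242000). MEG3 was near its floor in CRISPRi, at 0.321 CPM against 1345, and the pluripotency factor ZFP42 fell from 178 to 0.496 CPM (log2 −8.40, SE 0.23, adjusted p = 4.99e-34). GREB1L had 1 count against 1715, 1690-fold lower (303 to 66700), and OTX2, LHX5, the retinoic acid hydroxylase CYP26A1, PKDCC, FZD7 and SFRP1 were lower by log2 values of −4.03, −6.51, −5.12, −5.46, −2.98 and −2.56. Fibronectin (FN1) was higher by 3.23 (SE 0.10, adjusted p = 1.85e-32), the VEGF receptor KDR by 2.57, the surface protein THY1 by 1.99, IER3 by 4.33, OPTN by 2.43 and NANOG by 2.52. AC117402.1 had 832 counts against 2, a 422-fold ratio (117 to 3490).

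Mesendoderm and endoderm markers were higher in CRISPRi than in WTC. Of 10 mesendoderm and endoderm genes 8 were higher and 1 lower, the same adjusted over the list alone (camera adjusted p = 6.73e-06, adjusted p = 0.0293 with an estimated correlation). NODAL read 4.89, LEFTY1 4.18 and LEFTY2 3.93. Targets of p53 were higher (17 of 24 and 2 lower, 18 and 2 adjusted over the list alone, 4.29e-10, adjusted p = 0.0111 with an estimated correlation). The cell cycle inhibitor CDKN1A read 2.87, RRM2B 2.41 and the DNA repair gene DDB2 1.53. Metal response was higher (10 of 14 and 2 lower, the same adjusted over the list alone, 1.05e-11, adjusted p = 0.0293 with an estimated correlation). MT2A read 3.39 and MT1G 3.38. ATF4 targets were lower (26 of 27 and 1 higher, the same adjusted over the list alone, median −2.03, 8.57e-51, adjusted p = 0.0111 with an estimated correlation). ATF5 read −4.11 and PSAT1 −2.38. Imprinted genes were called lower (8 of 20 and 4 higher, the same adjusted over the list alone, 4.36e-05, adjusted p = 0.0117 with an estimated correlation). DLK1 read −3.69, GRB10 −0.94 and NNAT −0.91. Pluripotency was called up although members parted (15 of 25 higher and 6 lower, 16 and 7 adjusted over the list alone, 0.00130, adjusted p = 0.107 with an estimated correlation). POU5F1 read 1.24 and TDGF1 1.52, against the fall of ZFP42.

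AAVS1 neighbours were lower in CRISPRi than in WTC (7 of 21 and 2 higher, the same adjusted over the list alone, 0.00647, adjusted p = 0.289 with an estimated correlation). PPP1R12C read −2.33 (adjusted p = 5.71e-20), TNNT1 −1.80, TNNI3 −1.21 and COX6B2 −2.43. The nuclear-encoded respiratory chain (20 of 27, 20 adjusted over the list alone, 0.000274), the ER unfolded protein response (10 of 16 and 2 lower, the same adjusted over the list alone, 0.0103) and immediate early genes (9 of 18 and 3 lower, the same adjusted over the list alone, 0.00665) were higher. These also had adjusted p = 0.289 with an estimated correlation. Mitochondrial mRNAs were higher (11 of 13, 11 adjusted over the list alone, 3.21e-06, adjusted p = 0.237 with an estimated correlation). So were heat shock (11 of 16, 12 adjusted over the list alone, 4.36e-05, adjusted p = 0.0588 with an estimated correlation) and G2 and mitosis (17 of 20 and 1 lower, the same adjusted over the list alone, 4.47e-05, adjusted p = 0.206 with an estimated correlation). Cholesterol genes (9 of 23, 9 adjusted over the list alone, 0.0103) and glycolysis and hypoxia genes (11 of 25 and 3 lower, the same adjusted over the list alone, 0.0428) were higher, with adjusted p = 0.503 and 0.584 with an estimated correlation. VEGFA read −2.29. Not called were mesenchymal markers (6 of 13 higher and 6 lower, median −0.38, mean 0.28 and a test direction of up, 0.961), with COL1A1 at −3.06, and ZNF genes (84 of 494 higher and 91 lower, 0.571). Nor were DNA replication (4 of 21 higher and 8 lower, 0.236), cytosolic ribosomal proteins (15 of 81 higher and 2 lower, 0.15) or KRAB corepressor partners (2 of 17 higher and 4 lower). The same held for trophoblast markers (1 of 6 higher and 3 lower), cardiomyocyte markers (1 of 5 higher and 3 lower), the mitochondrial ribosome (9 of 23 higher and 2 lower) and interferon-stimulated genes (1 of 15 higher and 4 lower).

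Over all genes 3368 were higher and 3180 lower, 1047 and 1268 by over 2-fold, or 41.55% of those tested. The comparisons of CRISPRn and CRISPRi with WTC shared 1434 genes called in one direction: 696 higher, where independent lists would give 251.1, and 738 lower, where they would give 222.4, while 188 were called in opposite directions. Both use the same WTC libraries, which alone produce similarity. Across genes, which are not independent replicates, the log2 fold changes correlated at 0.519, where 20 simulations of unchanged groups against those libraries gave 0.47 on average and 0.512 at most. These correlations cannot show how much the shared libraries contribute, because all simulated changes were noise while many genes differed in the data. The covariance of the log2 fold changes was 0.338 against a simulated 0.0548, a difference of 0.283. Simulated groups shared 0 calls, but they had at most 1 call in each comparison. That 0 therefore cannot tell how many of the 1434 shared calls come from the shared libraries. The 2 WTC libraries were too few to give each line its own controls. Without WTC without doxycycline replicate A, 722 genes were shared.

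**Figure D4:**
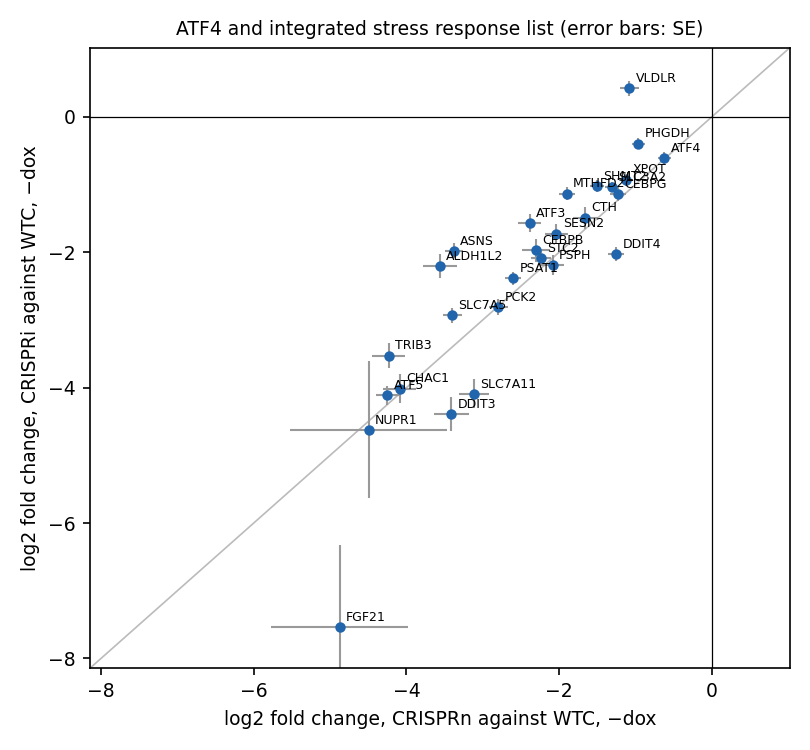
Log2 fold changes against WTC without doxycycline of the 27 ATF4 list members in CRISPRn (x) and CRISPRi (y), with standard errors as bars and the diagonal as a line. All 27 lie below 0 in CRISPRn and 26 in CRISPRi, where VLDLR, named after its values were seen, lies above 0.

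Between sgGCaMP and CRISPRi, the lines with and without the guide, differences were wide before doxycycline. In sgGCaMP the neural adhesion gene CDH2 was higher by 2.41 (SE 0.14), the axon guidance ligand SLIT2 by 3.71, the matrix protein TNC by 3.82, LDOC1 by 6.53, DUSP6 by 1.93 and DPYSL5 by 2.72. TFCP2 had 1 count against 552, 837-fold lower (150 to 33100), LINC01108 read −5.53, EGR1 −4.89, LHX4 −3.79, SERPINB9 −2.84 and PLAAT3 −2.03. GCaMP6f was higher in sgGCaMP by 0.45 (SE 0.08, adjusted p = 2.75e-05). ACTN2mKate was at least 473-fold higher in sgGCaMP, taking a floor of 3 counts over the CRISPRi group, and 373-fold higher with doxycycline (127 to 1810).

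Cholesterol genes were higher in sgGCaMP without doxycycline (20 of 23 and 1 lower, 20 and 2 adjusted over the list alone, camera adjusted p = 5.91e-26, adjusted p = 0.0231 with an estimated correlation). HMGCS1 read 1.82 and FDPS 1.09. Pluripotency was lower (17 of 25, 19 adjusted over the list alone, 4.90e-09, adjusted p = 0.0187 with an estimated correlation). ESRG read −0.80, E-cadherin (CDH1) −0.74 and DPPA2 −1.39. Targets of p53 were lower (19 of 24 and 1 higher, the same adjusted over the list alone, 3.24e-13, adjusted p = 0.0104 with an estimated correlation), RRM2B at −1.68 and CDKN1A at −1.50. Metal response was lower (10 of 14 and 1 higher, 11 and 1 adjusted over the list alone, 4.45e-11, adjusted p = 0.0328 with an estimated correlation), MT1H at −4.04. ATF4 targets were higher (18 of 27 and 1 lower, 20 and 1 adjusted over the list alone, 1.56e-12, adjusted p = 0.105 with an estimated correlation), SLC7A5 by 2.16. DNA replication was higher (13 of 21, 15 adjusted over the list alone, 2.17e-06, adjusted p = 0.0809 with an estimated correlation), RRM2 by 1.37. Lower were glycolysis and hypoxia (15 of 25 and 3 higher, 16 and 4 adjusted over the list alone, 1.64e-05, adjusted p = 0.238 with an estimated correlation), with PGK1 at −1.05, and immediate early genes (8 of 18 and 1 higher, the same adjusted over the list alone, 1.46e-06, adjusted p = 0.0843 with an estimated correlation). So were interferon-stimulated genes (5 of 15, 6 adjusted over the list alone, 0.0128, adjusted p = 0.0929 with an estimated correlation), with IFITM1 at −1.04, and ribosomal proteins (64 of 81 and 1 higher, 67 and 1 adjusted over the list alone, 1.03e-14, adjusted p = 0.239 with an estimated correlation). In all 2647 genes were higher and 2680 lower, 537 and 794 by over 2-fold, or 33.8% of those tested.

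With doxycycline in both lines, GCaMP6f was lower in sgGCaMP by a log2 value of −4.61 and VIM higher by 1.56 (SE 0.08, adjusted p = 2.72e-21). ISLR was higher by 3.11, CDH2 by 2.09 and TNC by 3.13, and LDOC1 had 759 counts against 3, a 237-fold ratio (80.9 to 1150), while TAGLN read −3.48, PDLIM1 −1.82, PYGL −1.59 and PLBD1 −1.93. Immediate early genes were lower (11 of 18, 11 adjusted over the list alone, camera adjusted p = 3.06e-16, adjusted p = 0.00819 with an estimated correlation), with EGR1 at −3.79, FOS at −2.78 and CCN1 at −1.84. Pluripotency (18 of 25, 20 adjusted over the list alone, 3.16e-15, adjusted p = 0.00322 with an estimated correlation) was lower, with CDH1 at −1.39 and EPCAM, an epithelial adhesion molecule, at −0.94. Targets of p53 (18 of 24 and 2 higher, 19 and 2 adjusted over the list alone, 3.10e-11, adjusted p = 0.00345 with an estimated correlation) and metal response (9 of 14, 10 adjusted over the list alone, 3.27e-13, adjusted p = 0.0244 with an estimated correlation) were lower. Cholesterol genes were higher (19 of 23 and 1 lower, the same adjusted over the list alone, 1.52e-17, adjusted p = 0.0424 with an estimated correlation). ATF4 targets (22 of 27 and 1 lower, 24 and 1 adjusted over the list alone, 1.13e-19, adjusted p = 0.0575 with an estimated correlation) were higher. So was DNA replication (10 of 21 and 1 lower, the same adjusted over the list alone, 4.66e-05, adjusted p = 0.101 with an estimated correlation). Glycolysis and hypoxia (17 of 25 and 1 higher, 18 and 2 adjusted over the list alone, 1.10e-12, adjusted p = 0.0591 with an estimated correlation) and ribosomal proteins (51 of 81 and 1 higher, 58 and 1 adjusted over the list alone, 3.48e-12, adjusted p = 0.321 with an estimated correlation) were lower. Interferon-stimulated genes were lower as well (2 of 15, 2 adjusted over the list alone, 0.0208, adjusted p = 0.108 with an estimated correlation). In all 1824 genes were higher and 2065 lower, 387 and 551 by over 2-fold, or 24.68% of those tested. Without and with doxycycline, 1287 genes were higher in both and 1403 lower in both, where independent lists would give 306.4 and 351.2, and 32 and 6 went opposite ways.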

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

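The genes listed first were picked out because the doxycycline effect of 1 line differed from that of another by an interaction term, and single libraries were not tested for their distance from the rest of their group. Of the 3 patterns weighed after them, VIM is among these genes, and the others are differences between lines without doxycycline. The interaction tests and line comparisons were planned, and the tests of explanations for the 3 patterns were chosen after the results were seen.

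The effect of doxycycline differed between CRISPRn and WTC for 64 genes, 14 with a higher and 50 with a lower effect in CRISPRn. The difference of log2 fold changes was 1.364 for VIM, 0.966 for PPP1R12C, which holds the AAVS1 site, and 0.786 for its neighbour TNNT1. In the stress genes ASNS and ATF5 it was 0.786 and 0.982, and in CUZD1, RWDD2B, SGK1, TCHP and MBTPS2 it was 0.76, 1.043, 1.352, 1.218 and 1.275. The bone and cartilage genes PTH1R and HAPLN1 read −2.119 and −2.616, STOM −1.485, the glutamate transporter SLC1A3 −1.47, HIP1R −1.13, HPDL −1.266, LHX4 −1.266, SIX3 −0.908, ENSG00000260834 −0.699 and SLC44A3-AS1 −1.077. The doxycycline effect on pluripotency genes was lower in CRISPRn than in WTC, where the list's median was 0.07 (3 of 25 genes, 4 adjusted over the list alone, camera adjusted p = 2.83e-06, adjusted p = 0.0842 with an estimated correlation): UTF1 read −1.021, NANOG −0.944 and L1TD1 −0.562. The effect on ATF4 targets was higher than in WTC, where their median was −0.10 (2 of 27, 5 adjusted over the list alone, 7.12e-05, adjusted p = 0.628 with an estimated correlation). Each interaction had 9 lists called by camera, and not all are named here. In CRISPRn p53 targets (camera adjusted p = 0.00847) and G2 and mitosis (0.00280) were also called higher. Mitochondrial mRNAs and cholesterol genes (0.00847 each) and neuroectoderm (0.0345) were called lower. With an estimated correlation 0 of these 9 lists were called in CRISPRn. The 64 calls became 23 without WTC without doxycycline replicate A, 34 without WTC with doxycycline replicate A, 27 without CRISPRn without doxycycline replicate A, 36 without WTC with doxycycline replicate B and 39 without CRISPRn with doxycycline replicate B. Without the first of these libraries NANOG had an adjusted p of 0.0542, CUZD1 0.173, SGK1 0.173, MBTPS2 0.371, RWDD2B 0.0856, TCHP 0.0619, ATF5 0.0666, L1TD1 0.0815, ENSG00000260834 0.0640 and SLC44A3-AS1 0.0780. Without CRISPRn without doxycycline replicate A ASNS had 0.190, and without WTC with doxycycline replicate A UTF1 had 0.205.

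Between CRISPRi and WTC the effect differed for 276 genes, 73 higher and 203 lower in CRISPRi. VIM read 2.227, the ERK phosphatase DUSP6 1.821, and the actin-binding CALD1 and TAGLN 0.819 and 1.163. PRTG read 1.437, SHISA2 1.626, TGFBI, a target of TGF-beta, 1.511, DTNA 1.145, CAPN6 1.993, TNNT1 0.755 and the mitotic motor CENPE 0.59. Lower were PLAAT3 (−1.264), SERPINB9 (−1.423), MMP24 (−1.706), PRODH (−1.077), TMEM64 (−1.209), PDLIM1 (−0.996), PTH1R (−1.993), ECEL1P1 (−2.001), STOM (−1.369), ENSG00000253507 (−1.369) and the chaperone HSP90AA1 (−0.58). The effect on pluripotency genes was lower in CRISPRi than in WTC (8 of 25, 10 adjusted over the list alone, camera adjusted p = 2.81e-10, adjusted p = 0.0195 with an estimated correlation), with UTF1 at −0.985, DNMT3B at −0.518, L1TD1 at −0.547 and TDGF1 at −0.598. So was that on metal response, with a median of 0.04 in WTC (7 of 14, 8 lower and 1 higher adjusted over the list alone, 4.00e-08, adjusted p = 0.113 with an estimated correlation), with MT1H at −1.973, MT1G at −1.392, MT2A at −1.205 and the zinc exporter SLC30A1 at −0.828. Cytosolic ribosomal proteins (6 of 81, 54 adjusted over the list alone, 3.15e-27, adjusted p = 0.229 with an estimated correlation) had RPS18 at −0.531, RPL27 at −0.478, RPL12 at −0.449 and RPL7A at −0.404. The effect on mitochondrial mRNAs was lower too (2 of 13, 11 adjusted over the list alone, 2.69e-07, adjusted p = 0.239 with an estimated correlation), with MT-ND1 at −0.494 and MT-CO2 at −0.394. The 276 calls became 85 without WTC with doxycycline replicate A, 132 and 150 without WTC without doxycycline replicates A and B, 183 without CRISPRi without doxycycline replicate B and 101 without CRISPRi with doxycycline replicate B. Without the first of these libraries the adjusted p was 0.247 for MT2A, 0.103 for MT1G, 0.110 for SLC30A1, 0.122 for UTF1, 0.0700 for L1TD1, 0.0804 for TDGF1, 0.0989 for RPS18, 0.269 for RPL27, 0.192 for RPL12, 0.227 for RPL7A, 0.0595 for MT-ND1, 0.174 for MT-CO2 and 0.177 for CENPE.

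Between sgGCaMP and CRISPRi the effect differed for 370 genes, 123 higher and 247 lower in sgGCaMP, among them GCaMP6f, the target of the guide, at −5.064. CLIP3 read 1.455, the MYC antagonist MXD4 1.298, SSTR1 2.694, PNRC1 1.265, VIM 0.75, USP9X 0.843, ESYT2 0.85, PMEL 0.714, SERPINB9 0.984, TMEM64 0.817, the repair gene DDB2 0.542 and the vector row rtTA3G_CRISPRi 0.617. DUSP6 read −2.06, DUSP5 −1.71, SPRY4 −1.208 and IER3 −1.656. Immediate early genes had lower effects in sgGCaMP (3 of 18, 5 adjusted over the list alone, camera adjusted p = 0.000714, adjusted p = 0.360 with an estimated correlation). On this list were MYC at −0.829, ARC at −1.987 and IER3, given above. TAGLN read −1.811, CALD1 −1.025, ERVH48-1 −1.522, AK4 −0.941 and ITPR2 −1.357. Mesendoderm genes had lower effects (2 of 10, 5 adjusted over the list alone, camera adjusted p = 2.32e-06, adjusted p = 0.0313 with an estimated correlation), with NODAL at −1.31 and WNT3 at −1.003. Cholesterol genes did too (5 of 23, 14 lower and 1 higher adjusted over the list alone, 2.34e-06), with MSMO1 at −0.652, HMGCS1 at −0.632 and INSIG1 at −0.822, as did the ER unfolded protein response (2 of 16, 3 adjusted over the list alone, 0.000174), with HSPA5 at −0.61 and CALR at −0.366. Both had adjusted p = 0.360 with an estimated correlation. The glucose transporters SLC2A1 and SLC2A3 read −0.682 and −0.535, BHLHE40, on the glycolysis and hypoxia list, −1.032, and MRPL3 −0.508. The 370 calls became 103 without sgGCaMP with doxycycline replicate A, 238 without sgGCaMP without doxycycline replicate A, 237 without CRISPRi without doxycycline replicate B and 168 without CRISPRi with doxycycline replicate B. Without the first of these libraries the adjusted p was 0.0851 for WNT3, 0.222 for DDB2, 0.419 for BHLHE40, 0.282 for CALR, 0.0807 for MRPL3, 0.121 for INSIG1, 0.0718 for rtTA3G_CRISPRi, 0.0949 for HMGCS1 and 0.0766 for SLC2A3, and without the last SLC2A1 had 0.0559.

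The first pattern was the rise of VIM with doxycycline in the 3 lines that carry a vector, which doxycycline itself would cause in WTC as well, and the smaller of the differences from WTC was 1.364 on the log2 scale, for VIM in CRISPRn (adjusted p = 6.01e-11). Mesenchymal cells would bring their collagens, and in sgGCaMP, where VIM rose from 100.2 to 725.2 CPM, COL1A1 read 42.3 and 34.9 CPM and the larger of the COL1A1 and COL1A2 log2 changes was 0.295 (SE 0.08), too little for the whole rise there. The mesenchymal list had 3 of 13 genes higher and 1 lower in sgGCaMP (4 and 1 adjusted over the list alone, median 0.29, camera adjusted p = 0.226) and was called up in CRISPRn (0.0273, adjusted p = 0.432 with an estimated correlation) and CRISPRi (0.0419, adjusted p = 0.396 with an estimated correlation), so a smaller part from such cells was not excluded. An effect on the chromosome segment around VIM stays open: of the 8 other tested genes within 500 kb, 2 rose in sgGCaMP, where 5.87% of all genes rose (exact hypergeometric p = 0.0761), 1 rose in CRISPRi and 0 in CRISPRn, too few to decide. The induced effectors remain a candidate explanation that the design names, untested in a line with the transactivator alone.

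The next pattern was the low level of ATF4 targets in CRISPRn and CRISPRi against WTC. If 1 WTC library stood apart, leaving it out would end the difference, and the median nearest 0 without 1 WTC library was −2.041. If the state were that of the WTC libraries without doxycycline alone, it would be absent with doxycycline, where the medians were −2.17 and −2.09. In sgGCaMP the median against WTC was −1.163, and 25 of 27 members were lower. The culture of WTC and the line itself cannot be told apart, because all WTC libraries hold both together, so higher stress in the WTC cultures may account for the difference as well as a change in the engineered lines.

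The last pattern was the 5327 genes that differed between sgGCaMP and CRISPRi without doxycycline. Leaky dCas9-KRAB guided by the sgRNA would lower GCaMP6f before doxycycline, and GCaMP6f was higher in sgGCaMP by a log2 value of 0.453. A difference between the lines in the reporter could hide a partial leak. The KRAB-dCAS9-P2A-mCherry row held 2 counts in CRISPRi and 3 in sgGCaMP without doxycycline. Gain or loss of whole chromosomes would shift the median of an autosome, and the autosome median farthest from 0 was 0.066. Of these genes 2690 differed in the same direction with doxycycline. The sgRNA, the derivation and culture of its line and what the ACTN2mKate row measures cannot be told apart, because they go together in all 4 sgGCaMP libraries.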

How the results depend on the processing

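Each lone sample left by leaving out a library was assumed to vary like the other groups. Thinning the libraries and the fit with line and doxycycline as terms were chosen after seeing the data, and the other alternatives were planned. Where a value moved, the cause was not tested, except that leaving out a library removes samples and thinning removes counts.

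Named genes reversed direction under 0 of the alternatives. Calls of named genes were lost for 35 of 677 with DESeq2 (5.2%), 36 of 665 after thinning (5.4%), 13 of 616 with the compared groups alone (2.1%), 10 with no filter (1.5%), 2 with RLE (0.3%), 0 with the replicate letter as a block and 460 of 3856 over the libraries left out (11.9%).

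Counts of genes moved by over 1.5 times as follows. For doxycycline in WTC 6 genes became 12 with no filter, 3 with DESeq2 and 13 with the compared groups alone, where 84.6% were higher in place of 100%, and 1 to 7 without 1 library. With DESeq2, doxycycline in CRISPRn, CRISPRi and sgGCaMP gave 219, 434 and 1503 genes in place of 361, 682 and 2338, and the sgGCaMP interaction 206 in place of 370. Without 1 library these 4 ranged over 80 to 262, 195 to 579, 791 to 1830 and 103 to 352. In CRISPRn 26.2% were higher without replicate A without doxycycline, in place of 39.1%, and in the sgGCaMP interaction 19.4% without sgGCaMP with doxycycline replicate A, in place of 33.2%. The mean effect gave 946 genes in place of 1800 with line and doxycycline as terms. The interaction of CRISPRn with WTC gave 40 after thinning and 99 with the block in place of 64, and 23 to 70 without 1 library. That of CRISPRi gave 161 after thinning in place of 276, and 85 to 301, and that of sgGCaMP 220 after thinning. CRISPRn against WTC gave 1100 to 1521 genes in place of 2277 without 1 library, and its overlap with CRISPRi 722 to 1015 in place of 1434. The counts of CRISPRi against WTC and of sgGCaMP against CRISPRi stayed within 1.5 times under the alternatives run.

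With an estimated correlation fewer lists were called: 1 in place of 6 for doxycycline in WTC, 0 in place of 11 in CRISPRn, 2 in place of 12 in CRISPRi, 3 in place of 11 in sgGCaMP and 1 in place of 9 for the mean. The interactions of CRISPRn, CRISPRi and sgGCaMP gave 0, 1 and 1 in place of 9 each, CRISPRn and CRISPRi against WTC 2 and 5 in place of 13 and 15, and sgGCaMP against CRISPRi 4 and 5 in place of 10 each. Without 1 library the sgGCaMP interaction gave 5 to 12 lists.

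Replicate letters were left out of the main fit by plan, because the design text names no batch. In a check for pairing, deviations from the group mean correlated at −0.047 to 0.152 between groups, and 2 of 28 pairs exceeded 0.1. With the letter as a block, doxycycline gave 8, 488, 898 and 2724 genes in WTC, CRISPRn, CRISPRi and sgGCaMP, in place of 6, 361, 682 and 2338. Some variation shared by letter was therefore not ruled out. A split of the libraries by letter called 0 genes, in a fit with line but not doxycycline as a term. Effects of doxycycline widened the spread in that fit, so its 0 does not settle the question. Thinning also lowered the counts for doxycycline to 244 in CRISPRn and 1573 in sgGCaMP, and depth was not separated from the number of libraries as a limit.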

Other observations

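The test of the ATF4 hypothesis and the autosome medians were chosen after the results were seen, and the count of other splits of the libraries and the comparisons of genes named by the rule were planned. CUBN, on the same side of VIM as TRDMT1 on chromosome 10 (16865963 to 17171830), encodes a kidney and gut receptor and had few counts. It was chosen after its values were seen, as were TRDMT1, ACTN2 and VIM-AS1. With doxycycline CUBN went from 2 to 30 counts in CRISPRi (adjusted p = 0.00288) and from 5 to 77 in sgGCaMP (adjusted p = 1.34e-07). In CRISPRn CUBN had an adjusted p of 0.307, and its interaction of CRISPRi with WTC had an adjusted p of 0.113. TRDMT1, an RNA methyltransferase gene (17184253 to 17244053), rose by 0.61 in sgGCaMP (adjusted p = 0.00346), and VIM-AS1, antisense to VIM, had an adjusted p of 0.0804 there.

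Around the AAVS1 site on chromosome 19, PPP1R12C was lower than in WTC by log2 values of −1.82 in CRISPRn and −2.33 in CRISPRi without doxycycline, at 23.1 and 16.3 CPM against 81.5. TNNT1, 15.2 kb away, read 0.04 in CRISPRn (adjusted p = 0.813) and −1.80 in CRISPRi (adjusted p = 9.86e-21). In CRISPRi, EPS8L1 at 3 kb read −0.89, RDH13 at 19.6 kb −0.47, TNNI3 at 34.2 kb −1.21, COX6B2 at 231.7 kb −2.43 and SHISA7 at 311.2 kb −2.61, while PPP6R1 and UBE2S read 0.23 and 0.28. DNAAF3, SYT5, TMEM86B, HSPBP1, BRSK1 and KMT5C, which lie between TNNI3 and COX6B2, did not pass the test in CRISPRi. Of 21 neighbours 7 were lower and 2 higher in CRISPRi, where 41.55% of all genes were called. In CRISPRn, IL11, ISOC2 and NAT14 were higher by 1.34, 0.39 and 0.36. There 3 of the 21 were higher and 1 lower, where 14.45% of all genes were called. Apart from PPP1R12C, TNNT1, TNNI3 and COX6B2, these members of the AAVS1 list were added after their values were seen and were not followed through the alternatives. With doxycycline PPP1R12C rose by 0.98 in CRISPRn and by 0.51 in sgGCaMP (adjusted p = 0.0203), with 0.31 in CRISPRi (adjusted p = 0.315) and 0.02 in WTC (adjusted p = 0.999). The call in sgGCaMP was lost without 3 of its libraries (adjusted p = 0.0569 and 0.155 without replicates A and B with doxycycline and 0.303 without replicate B without it). TNNT1 rose by 0.64, 0.61 and 0.80 in CRISPRn, CRISPRi and sgGCaMP and read −0.15 in WTC (adjusted p = 0.985).

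The gene ACTN2 itself did not pass the test: in sgGCaMP against CRISPRi it read −0.44 without doxycycline (adjusted p = 0.625) and −0.01 with it (adjusted p = 0.998). Medians of the 22 autosomes, over genes of moderate level and above, lay between −0.07 and 0.11 in CRISPRn against WTC and between 0.00 and 0.10 in CRISPRi against WTC.

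A hypothesis was that doxycycline blocks mitochondrial translation in WTC, as it does bacterial translation, and that ATF4 targets rise in response. The mean of the ATF4 list changed by −0.125 with doxycycline in WTC (95% interval −0.422 to 0.172, from the spread between libraries), an interval that holds no rise above 0.172. The list's mean in WTC was already higher without doxycycline (7.114) than in CRISPRn (4.735), CRISPRi (4.978) and sgGCaMP (5.718). Whether the list could rise further from that level was not tested. In CRISPRn 6 of 13 mitochondrial mRNAs also rose, though their list had a camera adjusted p = 0.278 with an estimated correlation. The change of the ATF4 list there was 0.139 (−0.158 to 0.436), which leaves the hypothesis open in CRISPRn. In CRISPRi it was −0.174 (−0.471 to 0.123) and in sgGCaMP −0.114 (−0.411 to 0.183). Another test set the doxycycline split of the 16 libraries against other splits into 2 and 2 within each line. Of 648 possible splits 60 were drawn, the real one included. With line and doxycycline as terms the real split called 946 genes and the highest other 58, so 1 of 60 was as large. Chance among these libraries is therefore unlikely. The splits cannot test chance differences between cultures, because the 2 libraries of a group may be technical replicates.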
